A study of Homo sapiens with 4 samples.

How the data were processed

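The data were 10x Genomics droplet libraries of labial minor salivary gland biopsies from 4 healthy donors, 1 library per donor. The deposited matrices hold UMI counts per gene and barcode, which the authors made with Cell Ranger 3.0.1 per the file headers, as whole numbers with no normalization. For each donor a filtered matrix (barcodes called as cells) and a raw matrix (all barcodes) were deposited, and a further copy of each filtered matrix was checked entry by entry and had 0 differing entries. The submitters' notes also name hg38 and Seurat 3.4, with roles not given, and no processed Seurat object or cell annotation was available. Class names therefore come from the steps below, not from the authors. The labels give a single group, so no comparison between donors was made, and donors served as replicates. The lists, markers, tests and alternatives were set before the data were examined, apart from those named below as later.

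Gene identifiers were matched to GENCODE 29 (33132 of 33694), and all 475 list and marker genes were found, 8 of them through their Ensembl identifier. Sex-linked transcripts were dropped (106 features). Barcodes were kept with at least 200 genes, at least 500 UMIs and at most 20% mitochondrial UMIs. Of 25809 barcodes, 1788 failed on genes or UMIs and 2214 on mitochondrial share. Doublets were scored per donor with Scrublet. Its automatic threshold called 209 doublets and none in donor 2, so the highest scores at an expected rate of 0.8% per 1000 cells were removed instead (1000 barcodes), a change made after seeing the data. The 20807 cells kept were scaled to 10000 UMIs and log transformed. The 2000 most variable genes, without readout genes, were scaled within each donor (values limited to 10), and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 1) gave 27 clusters.

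Each cluster took the name with the highest mean marker level relative to the other clusters, from fixed marker lists of 18 cell types. Where that was a secretory class, the secretory class with the highest marker level relative to empty droplets was taken. A cluster was left unnamed if fewer than 3 markers reached 10 CPM, or if its 10 top genes held no marker of the class or more markers of another. It was also left unnamed if every tested marker group reached at least 0.4 of its empty-droplet level. These naming thresholds were set after the clusters had been seen. They named 22 clusters in 11 classes (16981 cells) and left 5 clusters unnamed (3826 cells). Readout genes were left out of the top genes for this rule. In ductal cluster 8 (971 cells), 3 ductal and 3 serous markers were among the 10 top genes. With readout genes counted, there were 0 ductal markers and 1 marker of another class, and the rule would have left the cluster unnamed. Serous acinar cells of each donor fell largely into their own cluster. Empty droplets were barcodes of the raw matrices with 10 to 100 UMIs.

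UMI counts were summed per donor and class, with at least 20 cells per sum and at least 3 donors per class. The 16 sums of the mucous acinar, serous acinar, ductal and basal or myoepithelial classes were fitted together with edgeR (quasi-likelihood F test, TMM factors, donor as a block, two-sided), after the filterByExpr filter on low counts. The fit had 9 residual degrees of freedom, and the median dispersion was 0.0171. Adjusted p values are Benjamini-Hochberg values over the 12027 tested genes with a threshold of 0.05. A fit over all named classes compared ZG16B in each class with mucous acinar cells. Within a donor, sums of different classes deviated together (mean correlation across genes 0.489 over 24 pairs of sums, where genes are not independent replicates), so the donor block was kept. The mean of -0.161 between donors is no separate evidence, because each class was centred over its donors, which forces a negative value. Cells that define the classes also give the counts that are compared, so p values for genes that separate clusters are too small. Readout genes were kept out of the clustering features for this reason, but not the genes correlated with them.

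The 13 readout lists (351 genes) were secreted salivary proteins, mucin-type O-glycosylation, endoplasmic reticulum protein processing, transport and secretory receptors, MHC class II, MHC class I, interferon-stimulated genes, chemokines with cytokines and alarmins, ligands and receptors for cytotoxic lymphocytes, nuclear oxidative phosphorylation, dissociation and stress, epithelial transcription factors and viral entry factors. They were tested with limma camera on log CPM at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 13 lists. With the preset correlation 3, 10 and 7 lists passed in mucous against serous, mucous against ductal and serous against ductal. With an estimated correlation 1, 4 and 2 passed, and fry, which tests whether a set moves on balance in a direction, gave 3, 10 and 10. Named genes were ZG16B and, from each list, the 2 genes with the largest positive and the 2 with the largest negative fold change. These needed an adjusted p under 0.05, a mean of at least 20 CPM and the same direction in every donor. To these came, in each direction, the 5 largest under the same conditions among genes that are not clustering features, markers or readouts, and for other classes the gene of each list with the highest mean CPM. The text names only examples of them, and 4 genes that this rule took were left out of the table of named genes. Levels and shares are means with SD over donors. Donors held 43556906 to 60660566 UMIs in barcodes called as cells, so for abundant transcripts such as ZG16B the spread between 4 donors, not counting error, sets the precision. The epithelial sums held 539215 to 37034260 UMIs, so counting error adds to the spread for genes of low CPM in the smaller sums.

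The pipeline was tested on simulated data with the same dispersion for every gene, the fitted median of 0.0171. Of 100 genes changed 2-fold, 100%, 100% and 99% were recovered in the 3 comparisons, and 7, 6 and 6 unchanged genes were called. The real comparisons called far more genes, and real dispersions differ between genes. The recovery rates were not split by expression level and do not measure the effect of a shift in the median gene. They therefore cannot be carried over to the real gene counts. Alternatives set in advance were DESeq2, library totals, TMM without secreted proteins and markers, no filter, no donor block, only the compared classes, at least 50 cells per sum, cells thinned to 1000 UMIs, subtraction of the empty-droplet profile, mitochondrial limits of 10% and 40%, no doublet removal, Leiden resolutions of 0.5 and 2, features scaled over all cells, readout genes among the features, count splitting and leaving out each donor. Added after seeing the data were the Scrublet automatic threshold, doublets at 2 times the expected rate, the mucous class without its cluster highest in serous markers and the ductal class with only its cluster lowest in them. Tools were Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.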

Results

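Single-cell RNA was measured with 10x Genomics droplets in labial minor salivary gland biopsies of 4 healthy donors, who form a single group. The study's title ties a loss of ZG16B in saliva to graft-versus-host disease of the mouth, and no patient or saliva sample is among the data described here. All comparisons are therefore between cell classes of the same gland, made within each donor. The barcodes called as cells held 51708288, 43556906, 60660566 and 52857784 unique molecular identifiers (UMIs) in donors 1 to 4, in 7707, 7000, 4124 and 6978 barcodes. The median UMI count per barcode was 2222, 1427.5, 4410 and 2097.5. After filtering, 20807 cells remained. ZG16B (zymogen granule protein 16B, a secreted lectin-like protein; ENSG00000162078) is a protein-coding gene at chromosome 16, 2830169 to 2839585 on the + strand of GRCh38, with 6 annotated transcripts of 2 to 4 exons. It was the most abundant transcript of the glands, with 18.2% ± 2.10 (SD, n = 4 donors) of all UMIs in barcodes called as cells. The next were PIP with 5.96%, MUC7 with 5.85% and LYZ with 5.42% of UMIs, all of them secreted salivary proteins. Empty droplets also carried ZG16B, at 12.1% ± 5.77 of their UMIs (SD, n = 4), so droplets without a cell also yielded ZG16B UMIs. Mitochondrial UMIs made up 51.0%, 35.9%, 21.8% and 15.7% of the empty-droplet UMIs in donors 1 to 4. Without mitochondrial UMIs the ZG16B share of the empty droplets was 15.4%, 13.2%, 15.7% and 24.0%.

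Serous acinar cells, which secrete watery protein-rich saliva, were the largest named class, with 24.7% ± 10.0 of a donor's cells (SD, n = 4 here and below unless stated). Mucous acinar cells, named by MUC5B, BPIFB2 and TFF3, made up 10.8% ± 5.75, ductal cells 5.64% ± 2.18 and basal or myoepithelial cells 2.06% ± 1.45. Among the other classes, fibroblasts made up 14.1% ± 6.29, plasma cells 7.63% ± 5.16, vascular endothelial cells 7.57% ± 3.83 and T or NK cells 5.66% ± 1.62. Myeloid cells made up 2.62% ± 0.10, pericytes or smooth muscle cells 1.39% ± 1.18 and lymphatic endothelial cells 0.80% ± 0.64 (0.525% without donor 3). The pericyte or smooth muscle share (0.992% to 3.135% over all alternatives) is that of cluster 13 (273 cells). It leaves out unnamed cluster 5 (308 cells), which scored highest for the same class. The 10 top genes of the lymphatic cluster (147 cells) held 3 of its own markers and 2 of another cell type, and DCT and PMEL were among the 10. Cells in 5 clusters that met no class definition made up 17.1% ± 16.1 (10.2% without donor 2), most of them in 2 clusters with profiles like those of the empty droplets. No test was made on these shares.

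**Figure D1:**
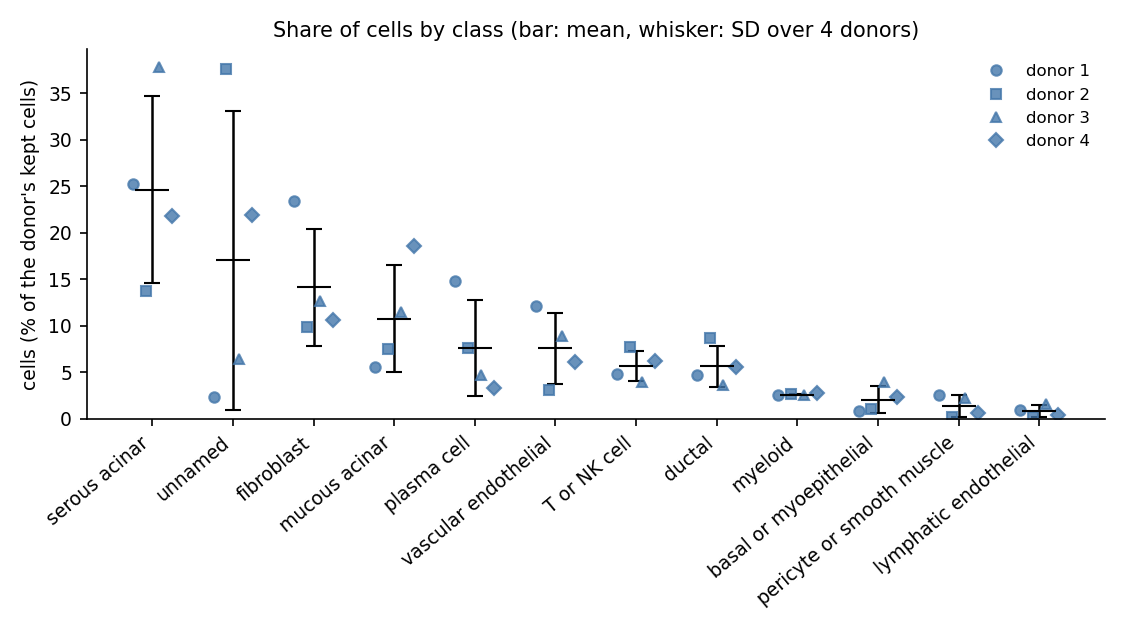
Share of each donor's filtered cells (y axis, percent) by cell class (x axis), with 1 symbol per donor, the mean as a horizontal bar and the SD over 4 donors as a whisker. Serous acinar cells have the highest mean, 24.7%, and the unnamed cells spread from 2.37% to 37.6% between donors.

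ZG16B was highest in serous acinar cells, where it made up 26.3% ± 1.09 of all UMIs. Basal or myoepithelial cells carried 20.3% ± 2.66, ductal cells 14.6% ± 3.77 and mucous acinar cells 12.9% ± 3.69. In the 7 non-epithelial classes the mean share lay between 1.23% and 2.60%. These levels depended on the processing. Over all alternatives they ran from 0.13% to 8.14% in T or NK cells, 0.69% to 8.24% in vascular endothelial cells and 1.04% to 11.4% in pericytes. The ratio of ZG16B to LYZ, PIP and MUC7 in all 26 non-epithelial sums was within 1.5 times that of the same donor's empty droplets, but so was that of serous cells. Of the ZG16B UMIs in a donor's filtered cells, serous acinar cells held 69.9% ± 11.5 and mucous acinar cells 12.0% ± 4.18. Ductal cells held 9.44% ± 9.97 (1.17% to 23.9%, with a mean of 4.61% without donor 2). These shares depend on which cells dissociation, capture and filters kept, and are not shares of the gland. The question of which gland cells carry ZG16B was tested by comparing every class with mucous acinar cells in a fit over all classes. ZG16B was 1.85 log2 higher in serous acinar cells (SE 0.41, adjusted p = 0.000373). It was -2.23 log2 in plasma cells (SE 0.41, adjusted p = 1.23e-05), where cluster 2 in donors 3 and 4 (23 and 13 cells at 15.2% and 15.8%) stood apart from their other plasma clusters (0.26% to 1.31%). It was between -4.90 and -3.31 log2 in T or NK cells, endothelial cells, fibroblasts, myeloid cells and pericytes (adjusted p of 2.36e-11 to 1.56e-08). Basal or myoepithelial cells, at 0.81 log2 (SE 0.40, adjusted p = 0.178), and ductal cells, at 0.01 log2 (SE 0.40, adjusted p = 1), did not pass the test. Ductal cells passed at -1.64 with only cluster 21 and at 1.44 without mucous cluster 16 (adjusted p of 0.00125 to 1 over all alternatives). The basal or myoepithelial value passed without donor 1 (1.32), with no filter (0.76) and without mucous cluster 16 (2.22). With at most 40% mitochondrial UMIs it was -3.64 log2, at 2.43% of UMIs, and passed in the other direction (adjusted p = 6e-08; 6e-08 to 0.934 over all alternatives). The serous value no longer passed after subtraction of the empty-droplet profile (1.75), with at most 10% mitochondrial UMIs (1.06) or with DESeq2 (1.74), and DESeq2 also ended the calls of plasma cells, T or NK cells and pericytes. Plasma cells also lost theirs without mucous cluster 16 (-0.77) and pericytes after subtraction (-6.45).

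The median cell lay below the class sum, least so in serous acinar cells. The median cell had 25.9% ± 1.17 of its UMIs from ZG16B among serous acinar cells, 9.71% ± 5.53 among ductal cells and 8.94% ± 7.81 among basal or myoepithelial cells. Among mucous acinar cells the median was 2.49% ± 0.93, against the 0.32% to 1.49% of the non-epithelial classes. The mucous class joined 3 clusters, in which ZG16B made up 18.8% ± 3.02 (cluster 16, n = 4), 7.79% ± 5.77 (cluster 10, n = 2; 11.9% in donor 1 and 3.71% in donor 3) and 3.88% ± 0.87 (cluster 14, n = 3) of UMIs. The ductal class joined cluster 8 at 16.5% ± 3.38 and cluster 21 at 6.35% ± 1.94 (n = 4 each). Cluster 8 held 971 of the 1233 ductal cells and had as many serous as ductal markers among its 10 top genes (3 each). With readout genes counted, these held 0 ductal markers and 1 of another class. Results for the ductal class therefore rest largely on a cluster whose name is uncertain. The name of cluster 21 is uncertain too. Its basal or myoepithelial markers stood at 8.85 times their empty-droplet level, against 7.33 times in basal or myoepithelial cluster 17. The share of cells with at least 1 ZG16B UMI was 99.9% to 100% in epithelial classes, at median depths of 5529 to 14616 UMIs. In non-epithelial classes it was 99.4% to 100%, at median depths of 997 to 7135 UMIs, so this share does not separate the classes.

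**Figure D2:**
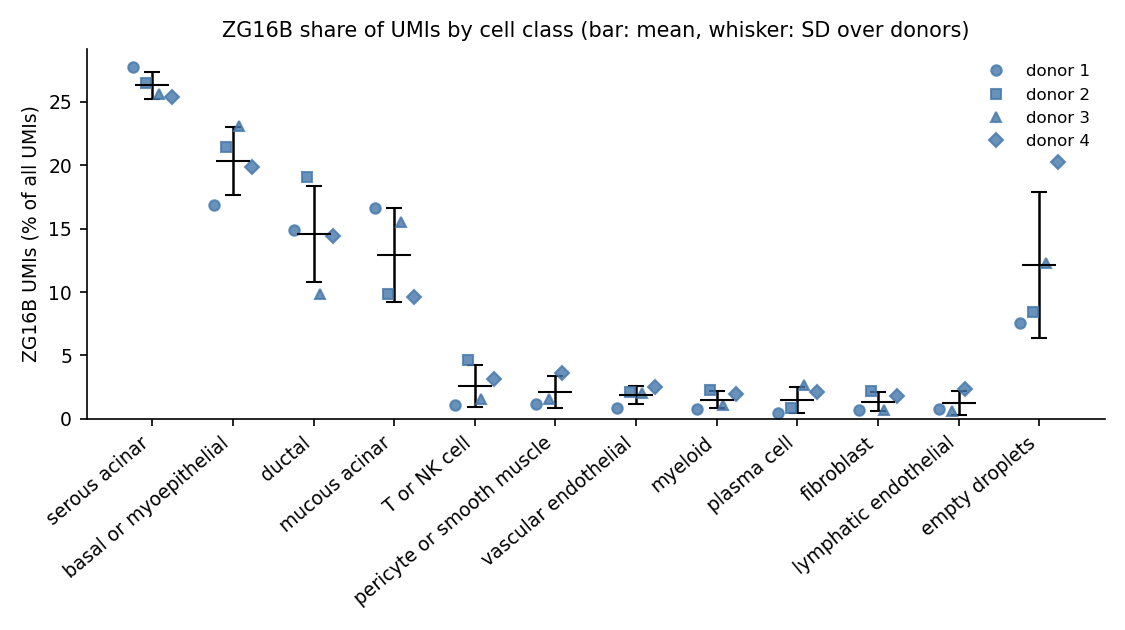
ZG16B UMIs as a percentage of all UMIs (y axis) in the summed cells of each class and in empty droplets (x axis), with 1 symbol per donor, the mean as a horizontal bar and the SD over donors as a whisker. Serous acinar cells average 26.3%, mucous acinar cells 12.9% and the non-epithelial classes 1.23% to 2.60%. The empty-droplet totals include mitochondrial UMIs, at 15.7% to 51.0% of UMIs between donors, whereas cells were limited to 20%.

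Mucous acinar cells carried less ZG16B than serous acinar cells, at a log2 fold change of -1.91 (SE 0.30, adjusted p = 5.34e-05), lower in 4 of 4 donors. Of 23 measured genes for mucin sugar chains, 16 were higher and 4 lower in mucous cells (3 of the 20 changed sign with library totals), led by GALNT12, which starts O-glycosylation, at 7.47 (SE 0.32, adjusted p = 1.75e-12). The secreted protein BPIFB1 was higher by 6.97 log2, at 280 ± 134 CPM (UMIs scaled to a common total per sum) against 1.37 ± 0.97, and the membrane mucin MUC16 by 6.67. Serous cells were higher in other secreted proteins: PIP, which is abundant in saliva, stood at -2.22 (SE 0.29) and OPRPN, the precursor of the peptide opiorphin, at -2.48 (SE 0.35). Of 12027 tested genes, 2527 were higher and 1949 lower in mucous cells at an adjusted p under 0.05.

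Mucin-type O-glycosylation genes had 16 of 23 measured members higher and 4 lower in mucous than in serous cells, with the same counts adjusted over the list alone, and 3 of the 20 changed sign when sums were scaled to library totals. The list was past the camera threshold with the preset correlation (adjusted p = 2.79e-07) and with an estimated correlation (adjusted p = 0.00926). ST6GALNAC1, a sialyltransferase, was higher by 5.64 log2, with 1 donor at 4.25 and the other donors at 6.17 to 6.54. The sialyltransferase ST3GAL1 was lower at -0.85, and was 0.06 when sums were scaled to library totals. Secreted salivary proteins had 8 of 29 measured genes higher and 15 lower, with the same counts adjusted over the list alone, and 2 of the 23 changed sign with library totals. Their median was -0.68 and their mean 0.40, and camera gave an adjusted p of 0.116, which passed under 7 alternatives (1.77e-13 with library totals; 1.77e-13 to 0.629 over all alternatives). Endoplasmic reticulum genes had 5 of 34 higher and 10 lower, or 5 and 12 adjusted over the list alone (adjusted p = 0.0821; 0.0245 without donor 3 and 0.0469 without donor 4, and 0.0109 to 0.659 over all alternatives), and 9 of the 15 changed sign with library totals. ERN2, a stress sensor of mucin-secreting epithelium, was higher by 6.37. SSR4, part of the translocon-associated complex, stood at -1.10, with 1 donor at -1.65 and the others between -1.01 and -0.88.

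Transport and secretory receptor genes had 9 of 27 higher and 4 lower in mucous than in serous cells, or 11 and 4 adjusted over the list alone (adjusted p = 0.745), and 3 of the 13 changed sign with library totals. SCNN1A, a subunit of the epithelial sodium channel, was higher by 3.24 log2 and the cotransporter SLC12A2 by 0.95, while carbonic anhydrase CA2 stood at -1.66. Epithelial transcription factors had 6 of 24 higher and 7 lower, or 9 and 7 adjusted over the list alone (adjusted p = 0.745), and 2 of the 13 changed sign with library totals. The forkhead factor FOXA1 was higher by 2.52, whereas the ETS factor ELF5 and the homeobox factor BARX2 stood at -1.32 each. Nuclear genes of oxidative phosphorylation had 0 of 34 higher and 13 lower, or 0 and 16 adjusted over the list alone, and 12 of the 13 changed sign when sums were scaled to library totals. Their camera adjusted p was 6.97e-07, and 0.697 with an estimated correlation. MHC class I genes had 0 of 15 higher and 8 lower, with the same counts adjusted over the list alone, and 6 of the 8 changed sign when sums were scaled to library totals. Their camera adjusted p was 0.00335, and 0.514 with an estimated correlation. B2M, the light chain of MHC class I, stood at -0.99, with 1 donor at -1.34 and the others between -0.90 and -0.84.

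The other 6 lists did not pass between mucous and serous cells, at camera adjusted p values of 0.365 to 0.875. With library totals, the MHC class II, interferon and chemokine lists passed (0.036, 0.0272 and 0.0247), and the stress list passed under 3 other alternatives (0.0174 to 0.045). Chemokines, cytokines and alarmins had 5 of 22 higher and 4 lower, of which 2 changed sign with library totals. CXCL17, a mucosal chemokine, was higher by 2.88 log2 and CCL28, also mucosal, stood at -1.13. MHC class II genes had 2 of 8 higher and 1 lower, and viral entry factors 3 of 8 higher and 1 lower, with the protease DPP4 at -1.62. Interferon-stimulated genes had 2 of 27 higher and 4 lower, ligands and receptors for cytotoxic lymphocytes 4 of 14 and 4, and dissociation and stress genes 2 of 23 and 3, and 3 of each changed sign with library totals. Adjusted over the list alone, these 6 lists gave 5 and 4, 2 and 1, 4 and 1, 2 and 2, 5 and 4, and 2 and 2. The endoplasmic reticulum list (median -0.18, mean 0.03), the MHC class II list (-0.19 and 0.23) and the interferon list (-0.12 and 0.10) had a median and mean of opposite sign, with the test direction down. The cytotoxic ligand list had a median of 0.19 and a mean of 0.10 with the test direction down. Outside all lists and clustering features, TSPAN1, a tetraspanin, was higher by 6.93 and CP, the copper carrier ceruloplasmin, by 6.88. HPSE, the enzyme heparanase, stood at -2.00 and PLTP, which transfers phospholipids, at -1.81.

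These values were relative to TMM factors. Scaling to library totals instead moved the median of all genes to 0.97 log2 and ZG16B to -1.03, or -2.00 relative to that median, gave 10306 genes higher and 178 lower, and changed the sign of 48 of the 140 readout genes past the threshold, while SSR4 (-0.20), B2M (-0.06) and CCL28 (-0.21) no longer passed. ZG16B was -1.04 with cells of at most 10% mitochondrial UMIs and -3.49 without cluster 16, and 1663 genes were higher without donor 4.

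**Figure D3:**
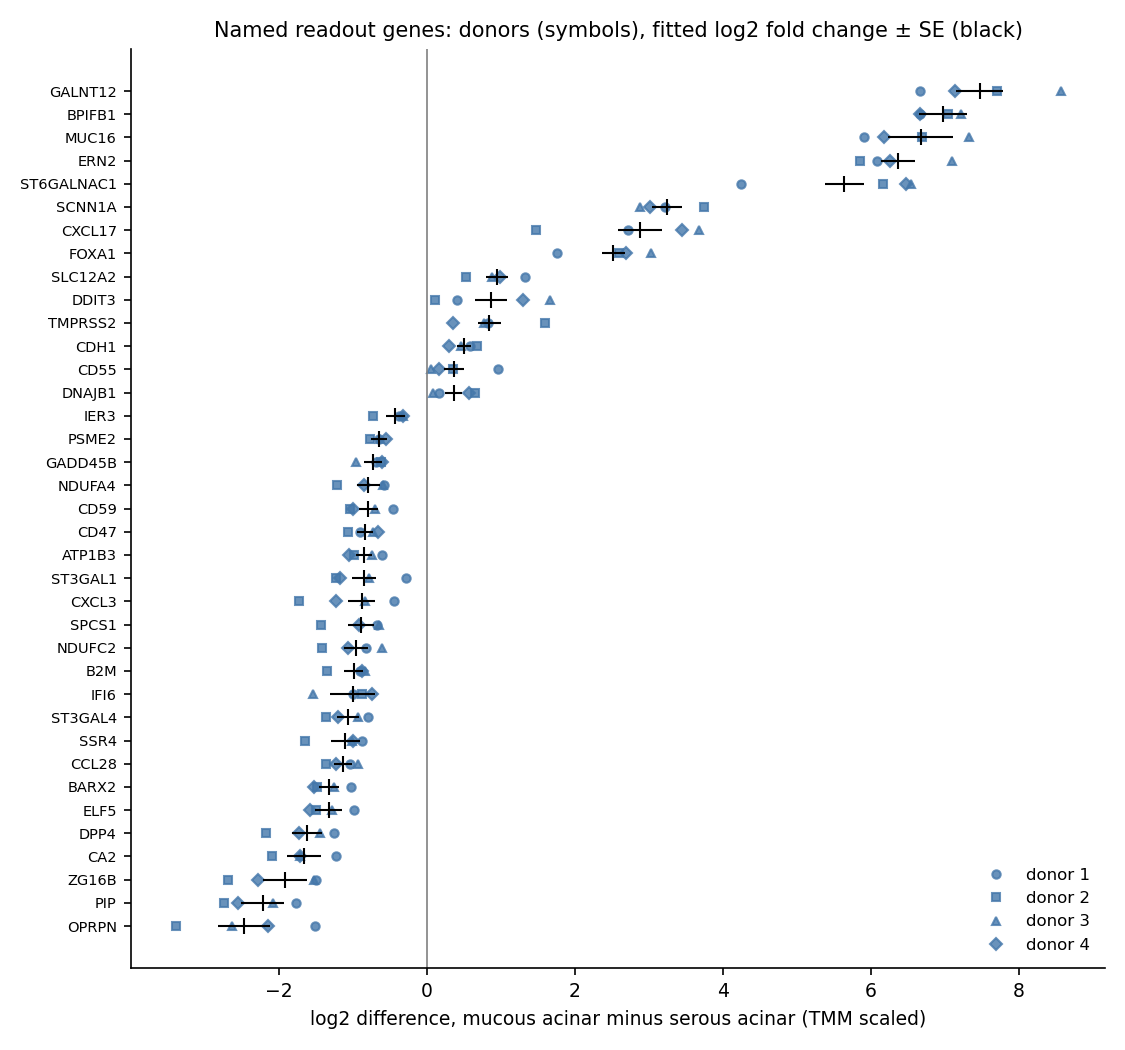
Log2 difference between mucous and serous acinar sums of the same donor (x axis, TMM scaled; symbols, 4 donors) for the named readout genes (y axis), with the fitted log2 fold change and its SE in black. GALNT12 lies at 7.47 and OPRPN at -2.48; ST3GAL1, SPCS1, ATP1B3, PSME2, CD47, CD59, NDUFA4, GADD45B and IER3 lie below 0 here and above 0 when scaled to library totals.

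The ZG16B difference between mucous acinar and ductal cells depended on the clusters in each class. It did not pass the test at -0.24 log2 (SE 0.30, adjusted p = 0.601), with mucous cells higher in 2 of 4 donors. It passed at 1.503 with only ductal cluster 21, the ductal cluster lowest in serous markers, and at -1.80 without mucous cluster 16. Cluster 21 is high in basal or myoepithelial markers and its name is uncertain, so the value of 1.503 may not be a comparison with ductal cells alone. Mucous cells were again higher in 16 of 23 mucin glycosylation genes and lower in 2, with GALNT12 at 5.15 log2 (SE 0.31, adjusted p = 5.7e-10). They were higher in the water channel AQP5, at 1.99 (870 ± 97.3 CPM against 224 ± 84.1), and in the muscarinic receptor CHRM3, at 1.33. Ductal cells were higher in the antimicrobial protein LCN2, at -3.67 (SE 0.44), the chaperone CLU, at -3.25, and genes of MHC class I antigen presentation and chemokines. Of 12027 tested genes, 1641 were higher and 1658 lower in mucous than in ductal cells. Scaling to library totals gave 1503 higher and 910 lower, and 0 of the 147 readout genes past the threshold changed sign. It moved the median of all genes only from -0.02 to 0.08, a shift that leaves little room for a change of sign.

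Mucin-type O-glycosylation genes had 16 of 23 higher and 2 lower in mucous than in ductal cells, or 17 and 4 adjusted over the list alone (camera adjusted p = 3.39e-08, and 0.00605 with an estimated correlation). Endoplasmic reticulum genes had 14 of 34 higher and 0 lower, or 19 and 0 adjusted over the list alone, with HERPUD1, of protein degradation at the reticulum, at 0.81. Their adjusted p was 1.51e-06, and adjusted p = 0.168 with an estimated correlation. MHC class I genes had 11 of 15 lower and 0 higher, or 12 and 0 adjusted over the list alone. The immunoproteasome subunit PSMB8 stood at -0.87 (adjusted p = 4.1e-07, and 0.036 with an estimated correlation). MHC class II genes had 6 of 8 lower and 1 higher, with the same counts adjusted over the list alone (adjusted p = 0.000421, and adjusted p = 0.165 with an estimated correlation). CD74, the invariant chain, stood at -1.96, with 1 donor at -3.37 and the others between -1.62 and -1.27, and CTSS, a protease of the same pathway, at -1.34. Interferon-stimulated genes had 11 of 27 lower and 1 higher, or 16 and 1 adjusted over the list alone, with IFITM3 at -1.51 (adjusted p = 5.21e-05, and adjusted p = 0.165 with an estimated correlation).

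Chemokines, cytokines and alarmins had 14 of 22 lower and 0 higher in mucous than in ductal cells, or 16 and 0 adjusted over the list alone (adjusted p = 1.51e-06, and 0.0134 with an estimated correlation). CXCL16 stood at -1.46 and CCL28 at -1.18, where ductal cells had 744 ± 227 CPM and mucous cells 335 ± 65.8. Epithelial transcription factors had 15 of 24 lower and 2 higher, with the same counts adjusted over the list alone (adjusted p = 2.42e-05, and 0.0134 with an estimated correlation). TFCP2L1 stood at -2.37 and FOXC1 at -1.49, against FOXA1 at 2.62. Secreted salivary proteins had 14 of 29 lower and 5 higher, or 14 and 6 adjusted over the list alone, with the trefoil peptide TFF1 at 3.74 (adjusted p = 0.00674, and adjusted p = 0.243 with an estimated correlation). Dissociation and stress genes had 9 of 23 lower and 1 higher, or 10 and 1 adjusted over the list alone, with GADD45B at -1.24. Their adjusted p was 0.00195, and adjusted p = 0.165 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 5 of 34 higher and 1 lower, or 2 and 1 adjusted over the list alone (adjusted p = 0.0368, and adjusted p = 0.59 with an estimated correlation). Without donor 1 or donor 3 their adjusted p was 0.128 or 0.341 (0.000416 to 0.65 over all alternatives).

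Transport genes (8 of 27 higher, 5 lower), ligands and receptors for cytotoxic lymphocytes (0 of 14 higher, 5 lower) and viral entry factors (0 of 8 higher, 1 lower) did not pass, at adjusted p values of 0.22, 0.0993 and 0.753. The cytotoxic list passed under 6 alternatives, among them without donor 2 (0.0413; 0.000213 to 0.583 over all alternatives). Adjusted over the list alone these counts were 10 and 6, 0 and 6, and 0 and 1. Outside the lists, PAPSS2, which makes the sulfate donor for sulfation, was higher in mucous cells by 5.19. ZG16B was 0.18 without donor 2. In cluster 21, led by S100A2, KRT14, KRT19, KRT15, RARRES1 and KRT5, basal or myoepithelial markers stood at 8.85 times and ductal markers at 5.12 times their empty-droplet level. With only cluster 21 as ductal, CCL28 was -0.03, the secreted list turned direction and the MHC class II, oxidative phosphorylation and stress lists no longer passed, and without donor 4, 1077 genes were higher and 878 lower.

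**Figure D4:**
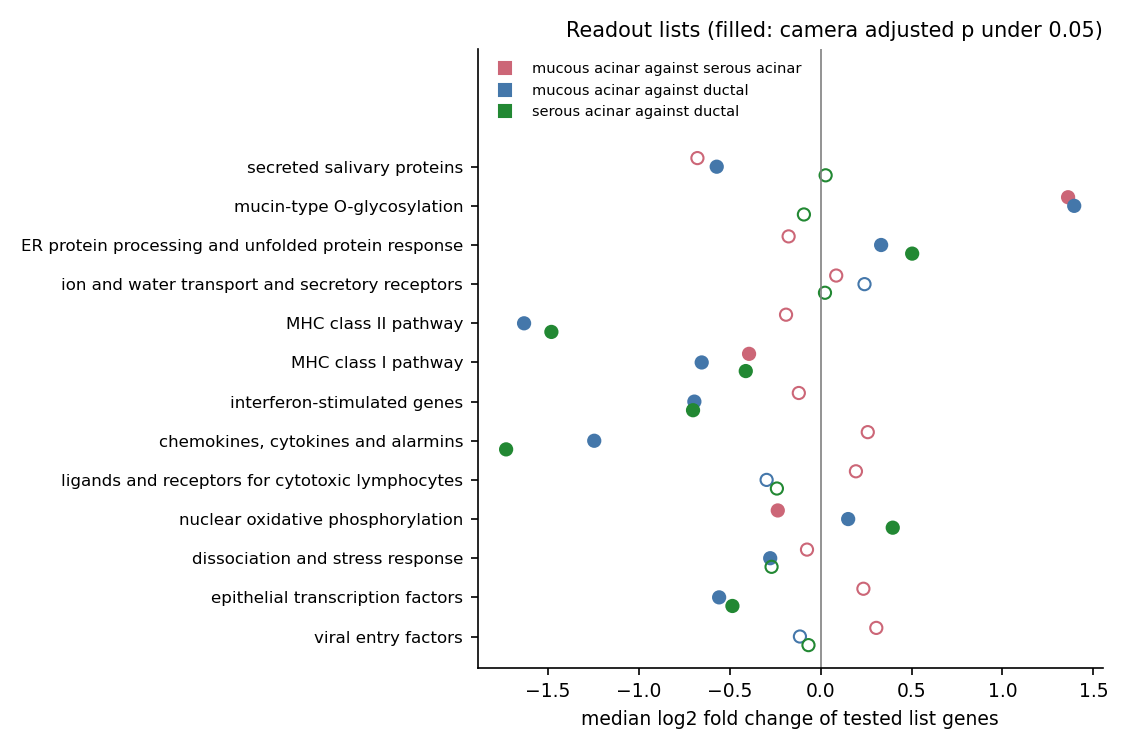
Median log2 fold change (x axis) of the measured genes of each readout list (y axis) in the comparisons of mucous with serous, mucous with ductal and serous with ductal cells; filled circles mark a camera adjusted p under 0.05 with the preset correlation. Mucin-type O-glycosylation lies at 1.36 and 1.39 in both mucous comparisons; against serous cells the oxidative phosphorylation and MHC class I medians are negative, where 12 of 13 and 6 of 8 called genes changed sign with library totals, which moved the median of all genes to 0.97.

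Serous acinar cells carried more ZG16B than ductal cells, by 1.67 log2 (SE 0.30, adjusted p = 0.000294), higher in 4 of 4 donors. They were also higher in the secreted protein C6orf58, by 2.39 (14060 ± 1027 CPM against 4780 ± 938), and in lactoperoxidase (LPO), an antimicrobial enzyme of saliva, by 2.38. Ductal cells were higher in the defensin DEFB1, at -5.27 (SE 0.28, adjusted p = 2.9e-10), in LCN2, at -3.88, and in chemokines and epithelial transcription factors. Of 12027 tested genes, 1826 were higher and 2220 lower in serous than in ductal cells.

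Chemokines, cytokines and alarmins had 16 of 22 lower and 0 higher in serous than in ductal cells, with the same counts adjusted over the list alone (camera adjusted p = 4.74e-06, and 0.0246 with an estimated correlation). CXCL17 stood at -3.00 and CXCL16 at -1.11. Epithelial transcription factors had 14 of 24 lower and 0 higher, or 15 and 0 adjusted over the list alone (adjusted p = 0.000109, and 0.0246 with an estimated correlation), with TFCP2L1 at -2.54 and the ETS factor ELF3 at -2.02. Endoplasmic reticulum genes had 25 of 34 higher and 1 lower, or 27 and 2 adjusted over the list alone, and 20 of the 26 called genes changed sign when sums were scaled to library totals. The chaperone CRELD2 was higher by 1.22 and the signal peptidase subunit SPCS1 by 1.15. The list's adjusted p was 9.5e-10, and adjusted p = 0.237 with an estimated correlation. Nuclear genes of oxidative phosphorylation had 24 of 34 higher and 0 lower, or 27 and 0 adjusted over the list alone, and 21 of the 24 changed sign when sums were scaled to library totals. UQCRQ, of respiratory complex III, was higher by 1.21, and the list's adjusted p was 1.36e-10, and adjusted p = 0.252 with an estimated correlation.

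MHC class II genes had 6 of 8 lower and 0 higher in serous than in ductal cells, with the same counts adjusted over the list alone and CD74 at -1.70 (adjusted p = 0.00263, and adjusted p = 0.252 with an estimated correlation). MHC class I genes had 7 of 15 lower and 0 higher, or 8 and 0 adjusted over the list alone (adjusted p = 0.0311, and adjusted p = 0.313 with an estimated correlation). Without donor 1, donor 3 or donor 4 that list's adjusted p was 0.0958, 0.0669 or 0.0828 (0.00422 to 0.752 over all alternatives). Interferon-stimulated genes had 15 of 27 lower and 0 higher, or 16 and 0 adjusted over the list alone, with IFITM3 at -1.73 (adjusted p = 0.000413, and adjusted p = 0.252 with an estimated correlation). Secreted proteins (11 of 29 higher, 13 lower), O-glycosylation (4 of 23 higher, 9 lower), transport (6 of 27 higher, 9 lower), cytotoxic ligands (0 of 14 higher, 3 lower), stress genes (0 of 23 higher, 9 lower) and viral entry factors (1 of 8 higher, 2 lower) did not pass, and 2, 2 and 1 genes of the first 3 changed sign with library totals. Adjusted over the list alone these were 12 and 13, 7 and 9, 7 and 10, 0 and 2, 0 and 9, and 1 and 3, at camera adjusted p values of 0.77, 0.92, 0.876, 0.24, 0.0593 and 0.77. The stress list passed under 6 alternatives, among them without donor 3 (0.0278; 1.87e-05 to 0.916 over all alternatives), the cytotoxic list with at most 10% mitochondrial UMIs (0.00422; 0.00422 to 0.912 over all alternatives) and the secreted list in the other direction with library totals (0.00345). The secreted list had a median of 0.03 and a mean of -0.95 with the test direction down, and the transport list a median of 0.02 and a mean of -0.27 with the test direction up.

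Outside the lists, the calcium-binding protein TESC was higher in serous than in ductal cells by 2.31 log2, and ANXA1, a phospholipid-binding annexin, stood at -5.56. Scaling to library totals moved the median of all genes to -0.89 and ZG16B to 0.85, or 1.75 relative to that median, gave 114 genes higher and 9599 lower, and ended the calls of the MHC class II, interferon and oxidative phosphorylation lists. ZG16B was 3.50 against ductal cluster 21, which is high in basal or myoepithelial markers and where the MHC class I, MHC class II and interferon lists did not pass. It was 1.08 with cells of at most 10% mitochondrial UMIs, and 1252 genes were lower without donor 4.

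**Figure D5:**
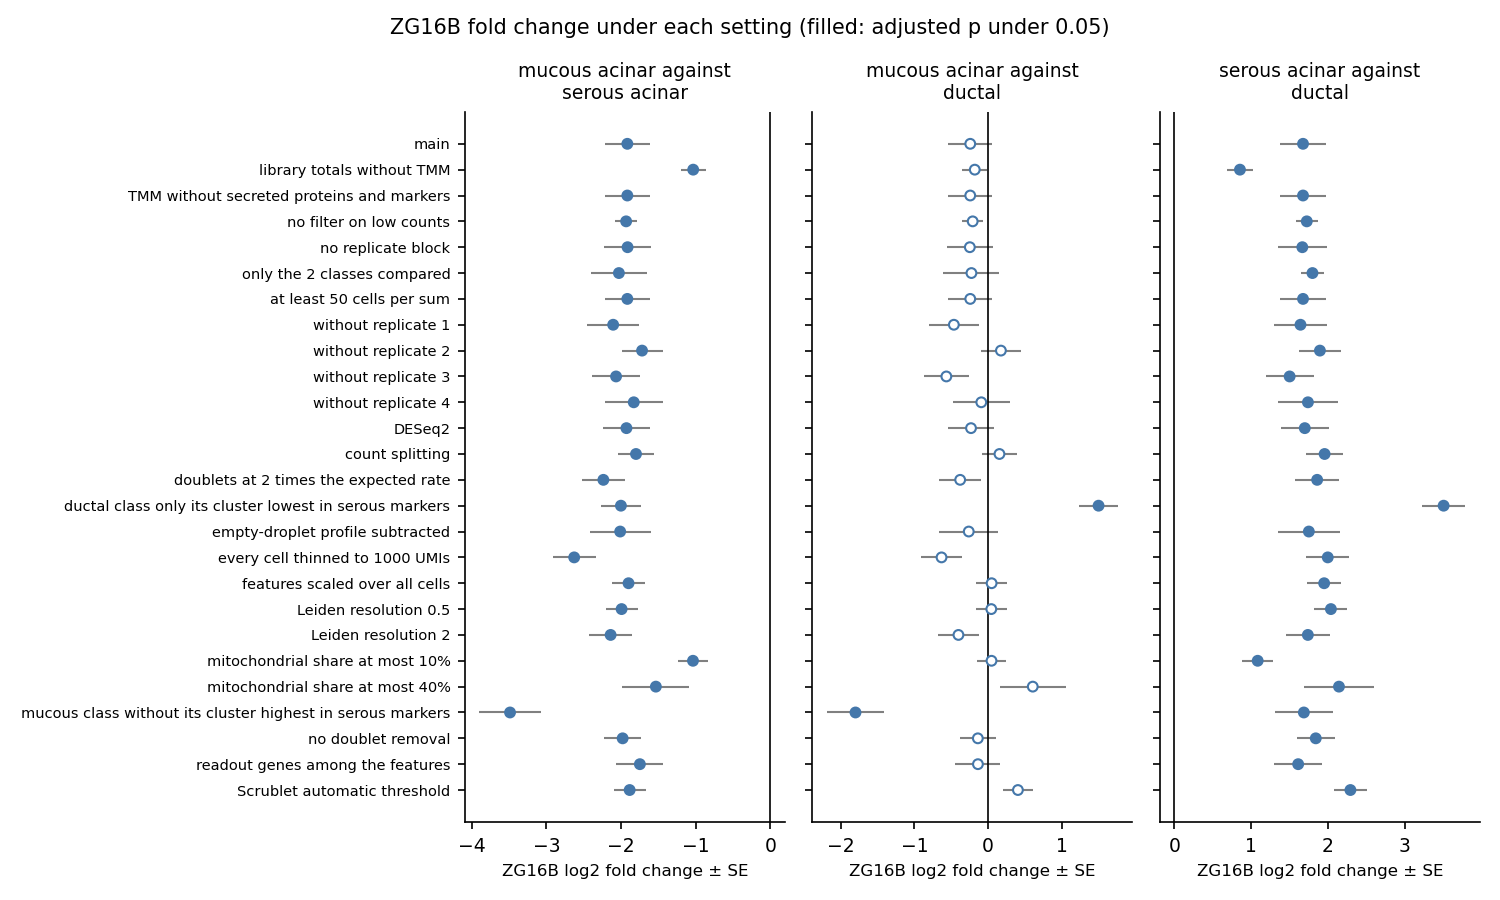
Fitted ZG16B log2 fold change with its SE (x axis) under each setting (y axis; replicates 1 to 4 are donors 1 to 4) in the 3 epithelial comparisons, with filled circles for an adjusted p under 0.05. Mucous against serous stays between -3.49 and -1.03, serous against ductal between 0.85 and 3.50, and mucous against ductal lies on both sides of 0, from -1.80 to 1.503.

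Plasma cells, which make the antibodies of saliva, carried mainly the IgA1 heavy chain among the heavy chain genes counted. IGHA1 made up 82.1% ± 6.07 (SD, n = 4) and IGHA2 6.70% ± 4.45 of the IGHA, IGHM and IGHG UMIs of plasma cells, or 88.8% ± 7.75 for both. IGHD was not counted, although it was among the top genes of plasma clusters 2, 19 and 22. IGHM made up 3.18% ± 2.49, IGHG1 3.52% ± 3.15, IGHG2 1.03% ± 0.93, IGHG3 2.86% ± 2.78 and IGHG4 0.58% ± 0.60. Without donor 2, IGHM was 1.955%, IGHG2 0.58% and IGHG4 0.29%, and without donor 4, IGHG1 was 2.16% and IGHG3 1.745%. The 4 IGHG genes together made up 7.99% ± 6.42. These shares rested on 158 to 904 plasma cells and 95948 to 802522 UMIs of the counted heavy chain genes per donor, and no test was made on them.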

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

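Chosen only after the result was seen were the tests of random doublets in cluster 16, of free RNA and serous RNA in basal or myoepithelial cells, and of free RNA in non-epithelial classes. The splits of the sums and the test of mixed RNA in cluster 16 were set before.

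In 5 of 159 groups of 4 donors' values, 1 donor lay far from the others. Chance gives this in about 1 in 20 independent groups. These groups share donors and TMM factors, so the number cannot be judged against that rate. Between mucous and serous acinar cells of a donor, ST6GALNAC1 differed by 4.25 log2 in 1 donor and by 6.17 to 6.54 in the others. SSR4 differed by -1.65 against -1.01 to -0.88 and B2M by -1.34 against -0.90 to -0.84, both in donor 2. In that donor the TMM factors of the mucous and serous sums (1.44 and 0.60) lay furthest apart. These factors enter every such difference of the donor, so the SSR4 and B2M values are not separate observations. IER3 differed by -0.72 against -0.38 to -0.32. Between mucous acinar and ductal cells, CD74 differed by -3.37 in 1 donor and by -1.62 to -1.27 in the others. No biological explanation was tested for these values.

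Cells outside the named classes formed 3 clusters that did not resemble empty droplets. Cluster 5 (308 cells) was led by ACTA2, TAGLN and MYH11, genes of smooth muscle contraction. Cluster 12 (36 cells) was led by ACTA1, TNNI2 and CKM, genes of skeletal muscle. Cluster 20 (403 cells) was led by HBB, LYZ and STATH, of red blood cells and serous secretion. STMN1, ODAM, TFF3, PTTG1, CD24 and CLDN10 were also among its top genes, and ZG16B made up 26.4% ± 6.21 of its UMIs (SD, n = 2). What these cells are was not tested. None of the 3 entered a comparison.

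The first pattern is serous RNA in a cluster of the mucous class: cluster 16 carried ZG16B at 18.8% ± 3.02 of UMIs (n = 4) beside MUC5B and TFF3. Random doublets at the assumed loading rate were too few. The cluster held at least 10.9 times the mucous and serous doublets that this rate gives, in every donor (77, 132, 163 and 350 cells). A higher real rate was not tested. The median cell of cluster 16 held 22881.5 UMIs, against 7559 and 8664 in mucous clusters 10 and 14. That depth leaves more than 1 cell per droplet open. In cluster 16, plasma cell markers stood at 0.052 times their empty-droplet level. Free RNA scaled to immunoglobulin UMIs gave ZG16B at 0.21% to 1.12% of the mucous class's UMIs, against 9.63% to 16.6% measured. These values argue against free RNA with the composition of the empty droplets as the main source. Mixed serous and mucous RNA in a droplet, as from cells that stayed attached, may be the source: 0 genes outside the clustering features stood above 2 times every other epithelial cluster. That test was weak, since 6 other clusters of the mucous, serous and ductal classes also gave 0 (cluster 10 gave 13 and cluster 21 gave 39). A cell type that makes both products stays open, and no biological explanation was tested.

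The next pattern is ZG16B in basal or myoepithelial cells, at 20.3% ± 2.66 of UMIs, with the median cell at 0.88%, 12.4%, 18.1% and 4.31% in donors 1 to 4. With at most 40% mitochondrial UMIs the level was 2.43%, at -3.64 log2 against mucous cells (adjusted p = 6e-08; 6e-08 to 0.934 over all alternatives). Free RNA with the composition of the empty droplets was excluded as the whole source in donors 1 to 3, where its subtraction, scaled to immunoglobulin UMIs, left at least 96.7% of the ZG16B UMIs and the share without mitochondrial UMIs was 1.21 to 1.74 times that of the empty droplets; in donor 4 (46.2% and 0.888 times) it cannot be told apart from RNA of serous cells. RNA of serous cells in the same droplet may account for it: the ratio of ZG16B to serous markers differed from that of serous cells by at most 1.27-fold in any donor. No biological explanation was tested.

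The last pattern is ZG16B in non-epithelial classes, at 1.23% to 2.60% of UMIs. Free RNA cannot be told apart from RNA of serous cells in the same droplet: the ratio of ZG16B to LYZ, PIP and MUC7 lay at 0.83 to 1.15 times that of the donor's empty droplets in all 26 sums, but that of serous cells also lay within 1.28-fold. Subtraction of the empty-droplet profile left no ZG16B in 10 of the 26 sums and up to 2.17% of the remaining UMIs in the others. The profile was scaled to immunoglobulin UMIs, except in plasma cells, where it was scaled to serous and mucous markers. In plasma cells all RNA of those markers is thereby taken as free RNA, so the subtraction cannot test the source of ZG16B there. No biological explanation was tested.

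The numbers of genes past the threshold were set against the 35 splits of the 8 sums of each comparison into groups of 4. Between mucous and serous cells the real split gave 4476 genes and the highest other 2, between mucous and ductal cells 3299 and 269, and between serous and ductal cells 4046 and 23. In each comparison 1 of 35 splits, the real one, gave as many. The sums are paired by donor, and 27 of the 35 splits put both sums of at least 1 donor on the same side. Among the 8 that part every pair, the real one included, the highest other gave 0, 1 and 1 genes, and 8 splits are too few for a share under 0.05. Clusters were formed on the same cells, so these splits do not test the definition of the classes.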

How the results depend on the processing

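The Scrublet automatic threshold, doublets at 2 times the expected rate, the mucous class without cluster 16 and the ductal class with only cluster 21 were chosen after the data had been seen; all other alternatives were set before. ZG16B stayed below serous cells in mucous cells under all 25 alternatives (-3.49 to -1.03 log2, highest adjusted p 0.014) and above ductal cells in serous cells (0.85 to 3.50, highest adjusted p 0.00534). Its difference between mucous and ductal cells kept its direction and stayed short of the threshold under 16 of 25. Counts of genes stayed within 1.5 times under 122 of 150 alternatives and counts of lists under 67 of 72. Named genes kept direction and call in 2882 of 3046 cases; 148 lost the call and 16 changed sign. List tests kept theirs in 857 of 936, where a sign change with no call in either setting is counted as kept. All 35 heavy chain shares moved by less than 1 SD. Most of these left out 1 of the 4 donors, which cannot move the mean by 1 SD, so they show no robustness. The same holds for leaving out a donor in class shares and ZG16B levels. Leaving out donor 2 or donor 4 moved 5 of the smaller heavy chain shares by more than 1.5 times (given with the shares). The minimum of 50 cells per sum changed no epithelial sum and says nothing. DESeq2 gives no list test, and a class with too few sums under an alternative has no value there. In the fit over all classes this left 23 of 24 alternatives for basal or myoepithelial cells, 18 for pericytes and 9 for lymphatic endothelial cells. Depth limits cells: thinning to 1000 UMIs lowered all 6 counts of genes. Unless the paragraph says otherwise, the cause of a change was not tested.

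Library totals moved the median gene (see the shifts given with each comparison) and with it the counts: 10306 genes higher and 178 lower in mucous than in serous cells, with 6 lists; 910 lower in mucous than in ductal cells; and 114 higher and 9599 lower in serous than in ductal cells. The chemokine list (adjusted p = 0.0247) and the oxidative phosphorylation list (0.135) turned direction between mucous and serous cells, as did secreted proteins between serous and ductal cells (0.00345). Between mucous and serous cells, ST3GAL1 was 0.061, SPCS1 0.012, ATP1B3 0.076, PSME2 0.28, CD47 0.082, CD59 0.12, NDUFA4 0.12, GADD45B 0.17 and IER3 0.49.

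Without the donor block, the counts were 1338 higher and 744 lower in mucous than in serous, 765 and 685 in mucous than in ductal, and 670 and 1217 in serous than in ductal cells. Thinned to 1000 UMIs, they were 544 and 475, 403 and 390, and 348 and 375, and CDH1 in serous against ductal cells was 0.05. With at most 10% mitochondrial UMIs, they were 1268 and 1070, 941 and 752, and 846 and 812, and CD55 in mucous against serous cells was -0.12. Without donor 4, 1663 genes were higher in mucous than in serous cells (1663 to 2341 over the donors left out), 1077 higher and 878 lower in mucous than in ductal cells (1077 to 1466 and 878 to 1492), and 1252 lower in serous than in ductal cells (1252 to 2115). The list count between mucous and serous cells was 5 without cluster 16, 5 without doublet removal and 5 with the Scrublet automatic threshold. With only cluster 21 as ductal, 2754 genes were higher in serous than in ductal cells, with 4 lists.

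ZG16B in mucous against ductal cells was 0.16 with count splitting, 1.503 with only cluster 21 as ductal, 0.049 with features scaled over all cells, 0.045 at Leiden resolution 0.5, 0.048 with at most 10% and 0.61 with at most 40% mitochondrial UMIs, 0.41 with the Scrublet automatic threshold and -1.80 without cluster 16. Leaving out a donor gave -0.57 (without donor 3) to 0.18 (without donor 2). Only the values 1.503 and -1.80 passed the threshold; over all its alternatives the adjusted p ran from 9.44e-05 to 0.925. With only cluster 21 as ductal, secreted proteins turned direction against mucous cells (adjusted p = 0.0459), ST3GAL4 was 0.44, C1GALT1C1 0.12 and CD59 0.47 in mucous against ductal cells, and CDH1 was 0.0028 and ATF3 0.012 in serous against ductal cells.

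In the fit over all classes against mucous cells, ductal ZG16B was -0.42 with count splitting, -1.64 with only cluster 21, -0.0052 after subtraction of the empty-droplet profile, -0.31 with features scaled over all cells, -0.15 at Leiden resolution 0.5, -0.13 with at most 10% and -0.69 with at most 40% mitochondrial UMIs, 1.44 without cluster 16, -0.032 with readout genes among the features, -0.54 with the Scrublet automatic threshold, and -0.35 (without donor 2) to 0.34 (without donor 3). Basal or myoepithelial ZG16B passed the threshold with no filter (0.76), without cluster 16 (2.22) and without donor 1 (1.32; range 0.63 to 1.32), and passed in the other direction with at most 40% mitochondrial UMIs (-3.64, adjusted p = 6e-08; 6e-08 to 0.934 over all alternatives). The serous value lost its call after subtraction (1.75), with at most 10% mitochondrial UMIs (1.06) and with DESeq2 (1.74). So did plasma cells without cluster 16 (-0.77) and with DESeq2 (-2.25), T or NK cells with DESeq2 (-3.12) and pericytes after subtraction (-6.45) and with DESeq2 (-3.60).

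The ZG16B share of UMIs moved by more than 1 SD in these cases, in percent. With no doublet removal it was 8.14 in T or NK cells, 4.85 in fibroblasts, 3.77 in myeloid cells, 4.02 in pericytes, 3.25 in plasma cells, 27.6 in serous cells and 8.24 in vascular endothelial cells. With the Scrublet automatic threshold it was 6.49 in T or NK cells, 2.20 in fibroblasts, 2.65 in myeloid cells and 8.20 in vascular endothelial cells. After subtraction of the empty-droplet profile it was 0.13 in T or NK cells, 0.14 in fibroblasts, 0.23 in lymphatic endothelial cells, 0.19 in myeloid cells, 0.36 in plasma cells and 0.69 in vascular endothelial cells. In plasma cells the profile was scaled to serous and mucous markers, in the other classes to immunoglobulin UMIs. With at most 10% mitochondrial UMIs it was 5.99 in T or NK cells, 18.4 in ductal cells, 18.7 in mucous cells, 3.41 in myeloid cells and 11.4 in pericytes. With at most 40% it was 2.43 in basal or myoepithelial cells, 10.4 in ductal cells and 23.4 in serous cells. It was 17.4 in basal or myoepithelial cells with count splitting, 17.5 there and 24.9 in serous cells with readout genes among the features, and 11.1 in basal or myoepithelial and 8.09 in mucous cells after thinning. Cluster 21 alone had 6.35, and mucous cells without cluster 16 had 5.69. The share of cells moved by more than 1 SD in myeloid cells (2.10 with at most 10% mitochondrial UMIs, 2.39 with count splitting). It did so in pericytes with at most 40% mitochondrial UMIs (3.13), no doublet removal (3.04), Leiden resolution 0.5 (2.97) and 2 (3.004), features scaled over all cells (3.01) and readout genes among the features (2.96).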

Other observations

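The comparison of each class with the mean of the other classes and the choice of the genes named here were made after the data had been seen. Fibroblasts were the class richest in the chemokine CXCL14, at 6872 ± 392 CPM (SD, n = 4 here and below unless stated), 7.79 log2 above the mean of the other classes (SE 0.31, adjusted p = 1.4e-25). Pericytes or smooth muscle cells carried the monocyte attractant CCL2 at 1910 ± 2317 CPM (n = 3), a spread larger than the mean. Vascular endothelial cells carried the water channel AQP1 at 1395 ± 104 CPM, the interferon-induced gene IFI27 at 2847 ± 952 CPM, the death ligand TNFSF10 at 762 ± 219 CPM and the transcription regulator ID1 at 1706 ± 390 CPM. Plasma cells carried SSR4, of protein translocation, at 3825 ± 265 CPM.

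Antigen presentation genes differed widely in level. Myeloid cells carried HLA-DRA, of MHC class II, at 13129 ± 2800 CPM, and vascular endothelial cells its partner CD74 at 2186 ± 613 CPM, against 131 ± 93.2 CPM in ductal, 39.1 ± 39.4 in mucous acinar and 23.7 ± 21.4 in serous acinar cells. B2M, of MHC class I, ran from 14788 ± 2005 CPM in T or NK cells and 11245 ± 1610 in vascular endothelial cells to 3338 ± 1225 in ductal, 2036 ± 727 in serous acinar and 1935 ± 681 CPM in mucous acinar cells. CPM values of the acinar classes are lowered by the share that ZG16B and other secreted proteins take. The dissociation and stress genes JUN and FOS varied between donors about as much as their mean, with JUN in ductal cells at 1003 ± 946 CPM and FOS at 712 ± 709 CPM.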
